A study of Homo sapiens
Mus musculus and Homo sapiens with 769 samples.

How the data were processed

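RNA of 769 samples was sequenced in a benchmark of scPLATE-Seq: 1 bulk HEK293 library, which the labels give as RNA-Seq, 192 HEK293 and 96 U87 single-cell wells, and 480 wells of a U87 and 3T3 mixture on 5 plates of 96 wells. The design text of the series names fewer mixture profiles than the labels hold, and all labelled wells were used. The authors deposited 4 tables of whole-number counts. Per the labels, 1 table holds read counts for bulk and single cells, 2 hold counts of UMIs (unique molecular identifiers, which mark single molecules) for single cells, and the fourth holds human and mouse UMI and read counts of each mixture well. The 2 UMI tables are named umi0 and umi1. What separates them is not given in the sources used here, and umi1, with fewer UMIs, was the main table. Reads were aligned with STAR 2.5.1a to hg38 and mm10, per the submitters' processing notes. The gene annotation, strandedness and UMI collapsing are not given in the sources used here. Columns were matched to samples by the names in the labels, with 0 columns left without a sample and 0 pairs of identical columns.

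Wells under 10% of their plate's median total were left out, except in median totals of mixture wells. This left 134 HEK293 wells (78 of plate 1, 56 of plate 2) and 95 U87 wells, and 96, 95, 86, 90 and 81 wells of the 15x SMRT, 12x Nextera, SPRI plates 1 and 2, the 15x SMRT, 8x Nextera, SPRI plate and the 12x SMRT, 12x Nextera plates with SPRI and Silane. Kept wells summed to 4112363 UMIs and 875074338 reads for HEK293 and 3141339 UMIs and 226877353 reads for U87. Read totals over all single-cell wells, left-out wells included, ranged from 3125 to 40463010 in HEK293 and from 8360 to 9993405 in U87. No doublet caller was run. HEK293 had 2 wells, and U87 0 wells, above 3 times the line's median, and plate 1 of HEK293 taken alone had 3.

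The labels name no cultures, so each group was treated as 1 sample and no test across cells was made. Counts were summed over kept cells and divided by the total to give CPM, counts scaled to a common total. Ratios have exact conditional binomial 95% intervals, shares exact Clopper-Pearson 95% intervals and medians order-statistic 95% intervals over wells. Counts under 3 over a group were set to 3 for ranking and list medians. A gene at 0 on 1 side has a fold bound against that floor, which is 0.96 CPM in U87 and 0.73 CPM in HEK293. Folds given as "at least" are this bound. The exact interval starts lower, for S100A6 at log2 11.08 in place of 11.37. A mixture well was called mixed when its minor species exceeded 10% of its counts. Mixture wells were grouped by plate, row and column. Rows were called mostly human or mostly mouse, and the minor and major species of a well were named, from the measured counts. Plate rows and columns come from the well names in the labels.

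Before the data were examined, 27 gene lists were fixed, together with the comparisons, the alternatives and the rule for named genes. A list member was measured with at least 10 counts over both sides, and a list needed 3 such members. Its median log2 ratio was placed among 10000 random lists of the same size, drawn for each member from the 50 genes on either side in mean expression. Percentiles outside 2.5 to 97.5 were called outside the random range, which describes these libraries and is no test. For variation, each cell was thinned without replacement to 18500 UMIs, the 10th percentile of kept cells rounded down, which left out 13 HEK293 and 10 U87 cells as too shallow. The Fano factor of a list's summed thinned UMIs was placed among random lists matched on mean. Bulk and summed single-cell reads were correlated over genes with at least 1 CPM on either side, with a pseudocount of 1.

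Named genes of the line comparison were the 12 at each end of the log2 ratio with at least 50 CPM in the higher line and the same direction against each HEK293 plate. To these came 2 to 4 members per list of largest absolute log2 ratio among those with at least 20 UMIs, and CDKN2A, CDKN2B and MTAP whatever their values. Some genes that the rule names are not reported here. For bulk they were the 10 at each end with at least 50 CPM and the same direction on both plates, and for variation the 12 genes of highest Fano factor per line with a mean of at least 0.5 thinned UMIs. Y-linked genes and the X inactivation transcript were left out by rule. Gene positions come from GENCODE release 29 on GRCh38. Of 22616 symbols counted in UMIs, 16952 matched 1 annotated gene, and of 24252 symbols counted in reads, 17815 did.

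Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for TMM factors only. The steps were tested on simulated data for U87 against HEK293 over 7211 genes. All 100 genes simulated with a 4-fold change were recovered at 2-fold or more, 0 of 7011 unchanged genes passed 2-fold, and the intervals covered 95.4% of true ratios. These counts had Poisson noise only, with no differences between plates or cells. They check the computation and do not show how often real ratios pass 2-fold. For variation within U87, a planted list reached percentile 100, and 4502 Poisson genes gave a median Fano factor of 0.99.

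Alternatives tried were no well filter or a filter at 25% of the plate median, thresholds of 5 and 20% for mixed wells, species scaled by their own upper wells, TMM and median-of-ratios scaling, the mean of per-cell CPM, listed genes from 1 count, the other UMI table, read counts, each HEK293 plate alone, a pseudocount of 0.1, no filter on low values, a thinning depth at the 25th percentile and a second random thinning. Chosen after seeing the data were reads instead of UMIs for mixture wells, and genes with at least 0.25 of the overall reads per UMI. Of 22610 genes 11713 reached this, and they held 62.1% of the UMIs of both lines, so the other UMIs lie on genes with fewer reads per UMI.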

Results

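The series holds 769 samples from a benchmark of scPLATE-Seq, a plate-based method for RNA sequencing of single cells. They comprise 1 bulk library of HEK293, a human embryonic kidney line transformed with adenovirus DNA, and 192 HEK293 single cells on 2 plates. The rest are 96 single cells of U87, a human malignant glioma line, and 480 wells of a mixture of U87 with 3T3, a mouse embryonic fibroblast line. The mixture wells fill 5 plates under 4 library conditions, which the labels describe as 15x or 12x SMRT, 12x or 8x Nextera, and SPRI or Silane. What the multiples count is not given in the sources used here. Each sample is 1 well, and the labels name no separate cultures. Each group therefore counts as 1 sample, with no replicate check. Intervals on shares and ratios cover counting error only.

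A kept HEK293 cell held a median of 29257.5 UMIs (95% interval of the median 27746 to 30654, 134 of 192 wells kept) from a median of 4717 genes. A kept U87 cell held a median of 30467 UMIs (28769 to 33647, 95 of 96 wells kept) from a median of 5064 genes. Thinned to 18500 UMIs per cell, HEK293 cells showed a median of 3855 genes (3819 to 3874, 121 cells) and U87 cells 4042 (4009 to 4076, 85 cells). The median HEK293 cell had 204 reads per UMI (199 to 216), against 69.3 in U87 (63.7 to 73.5). Plate 2 of HEK293 kept 56 of 96 wells and plate 1 kept 78 of 96. UMI totals of kept wells ranged from 2345 to 152822 in HEK293 and from 4211 to 91137 in U87. The deposited alternative UMI table gave a higher HEK293 median of 47362.5 UMIs and a lower 125 reads per UMI.

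The mixture of human and mouse cells addresses how far the molecules of a well come from 1 species. Every plate of the 15x SMRT, 12x Nextera, SPRI condition showed a minor species above 10% of UMIs in most kept wells, 73 of 96 on plate 1 (76.0%, exact Clopper-Pearson 95% interval 66.3 to 84.2%) and 77 of 95 on plate 2 (81.1%, 71.7 to 88.4%). The 15x SMRT, 8x Nextera, SPRI plate had 32 of 86 such wells (37.2%, 27.0 to 48.3%). The 12x SMRT, 12x Nextera plates had 54 of 90 with SPRI (60.0%, 49.1 to 70.2%) and 37 of 81 with Silane (45.7%, 34.6 to 57.1%). Counted on reads instead of UMIs, the same plates had 2, 0, 0, 5 and 0 mixed wells. With each species scaled by its own upper wells, the shares of mixed wells were 95.8, 96.8, 1.16, 32.2 and 1.23%.

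The median minor-species share of UMIs was 17.8% on plate 1 (15.3 to 18.6%) and 16.1% on plate 2 (15.0 to 16.9%) of the 15x SMRT, 12x Nextera, SPRI condition. It was 8.56% (3.12 to 9.96%) with 8x Nextera, 13.6% (8.62 to 14.8%) with 12x SMRT and SPRI, and 9.46% (2.89 to 10.6%) with 12x SMRT and Silane. On these last plates the row medians were 2.69 to 2.88, 4.49 to 6.47 and 2.39 to 2.72% in the mostly human rows a, c, e and g. In the mostly mouse rows b, d, f and h they were 10.3 to 11.8, 14.8 to 16.4 and 10.7 to 12.0%. The plate medians lie between both sets of rows. They and the mixed shares thus depend on how many wells of a plate are mostly mouse. On reads the plate medians were 3.48, 3.305, 2.63, 3.53 and 2.37%. Median UMI totals over all 96 wells of a plate were 27153 and 25834.5 on the 15x SMRT, 12x Nextera, SPRI plates, 18788.5 with 8x Nextera, 21190.5 with 12x SMRT and SPRI, and 15001 with Silane. Human UMIs exceeded 90% in 23, 18, 42, 36 and 39 kept wells of these plates. They stayed under 10% in 0, 0, 12, 0 and 5 wells by UMIs, but in 59, 61, 44, 43 and 42 wells by reads. Condition and plate coincide except for the condition with 2 plates, and sequencing depth per plate was not controlled. The arrangement of human and mouse wells in rows also differed between the 15x SMRT, 12x Nextera, SPRI plates and the others. Differences in mixed shares can therefore not be assigned to the library condition.

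**Figure D1:**
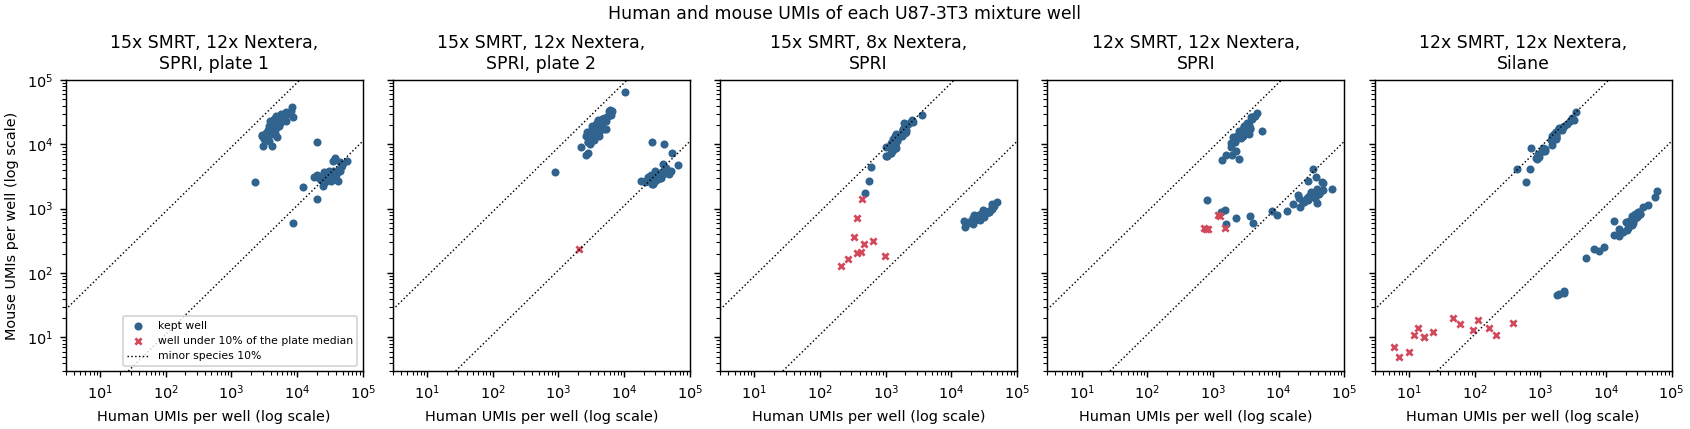
Human UMIs (horizontal, log scale) and mouse UMIs (vertical, log scale) of each mixture well, with 1 panel per plate. Dots are kept wells, crosses are wells under 10% of the plate's median total, and between the dotted lines the minor species exceeds 10%, which holds for 73, 77, 32, 54 and 37 kept wells from left to right.

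Human and mouse wells followed plate rows on 3 of the 5 plates. On the 15x SMRT, 8x Nextera, SPRI plate the median human share was 97.1 to 97.3% in rows a, c, e and g and 10.3 to 11.8% in rows b, d, f and h. The corresponding ranges were 93.5 to 95.5% and 14.8 to 16.4% for 12x SMRT with SPRI, and 97.3 to 97.6% and 10.7 to 12.0% for Silane. Row medians on the other two plates ran from 19.8 to 87.7% and from 17.9 to 79.2%, without that alternation. The median minor share by plate column lay between 9.07 and 19.7% on plate 1 and between 11.3 and 18.9% on plate 2 of the 15x SMRT, 12x Nextera, SPRI condition.

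**Figure D2:**
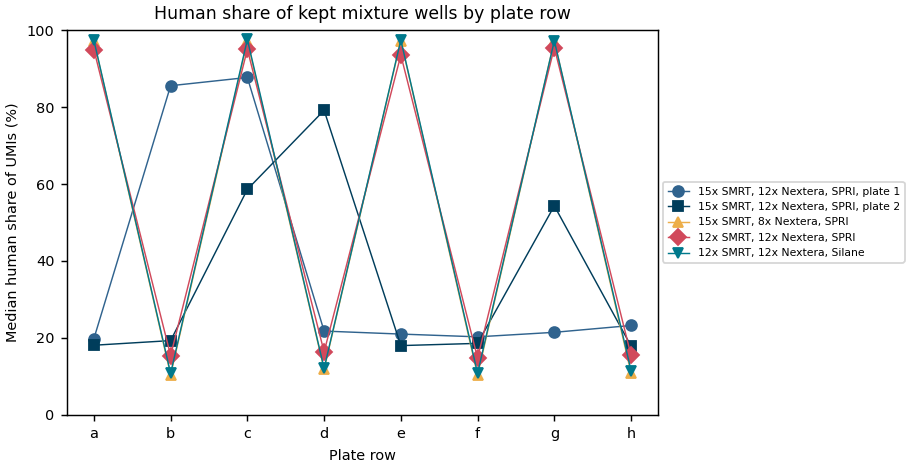
Median human share of UMIs (percent) of the kept wells in each plate row a to h, with 1 line per mixture plate. Rows a, c, e and g of 3 plates lie at 93.5% or above and rows b, d, f and h of those plates at 16.4% or below.

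The series holds 2 human lines profiled as single cells, and the comparison of U87 with HEK293 gives the genes and gene groups that differed between these libraries. The labels give no library condition for either line, so whether both were prepared alike is not known. Genes of contractile, matrix-producing cells were far higher in U87. S100A6, a calcium-binding protein of mesenchymal cells (chromosome 1, 153534599 to 153536244, GRCh38), had 6086 UMIs over the U87 cells and 0 over the HEK293 cells, at least 2656-fold higher. SPP1, which encodes the secreted phosphoprotein osteopontin (chromosome 4, 87975650 to 87983426), had 2639 and 0 UMIs, at least 1152-fold higher. MYL9, a regulatory myosin light chain, had 1458 and 0, at least 636-fold higher. In the opposite direction, SOX4, a developmental transcription factor (chromosome 6, 21592768 to 21598619), had 1 UMI in U87 and 2497 in HEK293, a log2 ratio of -10.90 with a counting interval of -16.20 to -8.42.

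Of the 12 genes highest in U87, SCG5, a secretory granule protein, had 1154 UMIs against 0 (at least 504-fold), and PRKCDBP, a caveola component, had 828 against 0 (at least 361-fold). The noncoding LINC01444 had 1393 against 0 (at least 608-fold). AC002398.12 had 1213 against 0 (at least 529-fold), with only 1734 reads behind those UMIs. OCIAD2 had 1536 UMIs against 2 (log2 9.97, 8.12 to 13.02). FOSL1, a subunit of the AP-1 transcription factor, had 1479 against 4 (log2 8.92, 7.56 to 10.80), and the proteoglycan gene SRGN had 1272 against 4 (log2 8.70, 7.34 to 10.58). The metallothionein MT1E had 821 against 1 (log2 10.07, 7.59 to 15.38) and the matrix protein TGFBI 795 against 1 (log2 10.02, 7.54 to 15.33).

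Of the 12 genes highest in HEK293, RP4-735C1.4 had 3758 UMIs against 0 in U87 (at least 957-fold lower in U87), with 20555 reads behind them. CDKN2A, which encodes the cell cycle inhibitors INK4A and ARF, had 1025 against 0 (at least 261-fold lower), and GAL, the neuropeptide galanin, had 842 against 0 (at least 214-fold lower). CA2, a carbonic anhydrase, had 2972 UMIs in HEK293 and 14 in U87 (log2 -7.34, -8.21 to -6.59). CALCB, a calcitonin gene-related peptide, had 580 against 0 (at least 148-fold lower), and GSTM3, a glutathione transferase, had 540 against 0 (at least 137-fold lower). HOXA10, a homeobox gene of posterior patterning, had 574 against 0 (at least 146-fold lower). Its neighbours HOXA-AS3 (544 UMIs in 28 cells) and HOXA10-AS (472 UMIs in 40 cells) were also at 0 in U87. Behind the HEK293 UMIs of HOXA10, HOXA-AS3 and HOXA10-AS stood 24280, 3449 and 6013 reads, far fewer per UMI than the 204 of the median HEK293 cell. These neighbouring and overlapping transcripts are uncertain individually, since the strandedness of counting is not given. TTN, the giant muscle protein titin, had 478 UMIs in 33 HEK293 cells against 3 in U87 (log2 -6.93, -9.21 to -5.37, and -4.05 on reads). CXADR, the coxsackievirus and adenovirus receptor, had 453 against 3 (log2 -6.85, -9.13 to -5.29), with 10998 reads behind the HEK293 UMIs.

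The mesenchymal list stood highest, with 21 of 24 measured members at least 2-fold higher in U87, 0 at least 2-fold lower and a median log2 ratio of 4.10, above all of 10000 expression-matched random lists. TAGLN, the actin-binding protein transgelin, had 699 UMIs against 3 (log2 8.25, 6.70 to 10.53). In the extracellular matrix list 19 of 24 members were higher and 2 lower (median 2.38, percentile 100). The urokinase gene PLAU had 212 UMIs against 1 (log2 8.12, 5.62 to 13.43). The gelatinase gene MMP2 had 105 against 1 (log2 7.10, 4.59 to 12.42), and the collagen gene COL1A2 had 242 against 7 (log2 5.50, 4.44 to 6.83). Of 13 YAP and TEAD targets 11 were higher and 0 lower (median 3.23, percentile 100), among them ANKRD1 with 135 UMIs against 0 (at least 58.9-fold), CTGF at log2 4.33 (3.55 to 5.22) and F3, the tissue factor gene, at log2 4.35 (3.38 to 5.51).

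Immune and stress-signalling lists were also higher in U87. Of 16 interferon response genes 11 were higher and 2 lower (median 1.87, percentile 99.99), with the ubiquitin-conjugating enzyme gene UBE2L6 at log2 4.97 (4.11 to 5.99) and the ubiquitin-like ISG15 at 4.32 (3.51 to 5.25). Of 7 NF-kB targets 6 were higher and 0 lower (median 2.56, percentile 99.99), with the inhibitor NFKBIA at 2.56 (2.26 to 2.88) and the chemokine CXCL8 at 5.52 (2.95 to 10.86, 35 UMIs against 1). Of 16 MHC class I and antigen processing genes 8 were higher and 0 lower (median 0.97, percentile 99.8), with B2M, the MHC class I light chain, at 3.27 (3.20 to 3.35) and the immunoproteasome subunit PSMB8 at 170 UMIs against 0 (at least 74.2-fold). On read counts the MHC list had a median of 0.38, inside the random range at percentile 85.7. Of 14 immediate early genes 8 were higher and 1 lower (median 1.33, percentile 99.9). JUNB was at 2.95 (1.91 to 4.15, 53 UMIs against 9). EGR1 was at 3.20 (1.45 to 5.58), from 21 UMIs in 6 U87 cells with 59 reads, against 3 UMIs in HEK293. Of 5 blood and immune markers 3 were higher and 1 lower (median 1.57, percentile 97.505). The macrophage marker CD68 was at 1.57 (1.20 to 1.95, and 5.11 on reads) and the actin-bundling LCP1 at 4.89 (3.28 to 7.20). The percentile of the blood and immune list was 97.1 under TMM and 96.8 under the median of ratios, inside the random range. Such scaling shifts a list and its random lists alike, so this change comes only from the matching of random lists. It shows that the list lies at the edge of the range.

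Neuronal and kidney-patterning lists were lower in U87. Of 13 neuronal genes 8 were lower and 4 higher (median -2.20, percentile 0.030), with the neurofilament genes NEFL at 0 UMIs against 120 (at least 30.6-fold lower) and NEFM at 0 against 92 (at least 23.4-fold lower). With every listed gene of at least 1 count the neuronal median was -0.064 at percentile 69.4, with the alternative UMI table -0.81 at 19.3 and with reads -0.99 at 4.23, all inside the random range. Of 14 kidney and patterning factors 10 were lower and 1 higher (median -1.77, percentile 0.050). HOXC10, another posterior homeobox gene, had 1 UMI in U87 and 57 in HEK293 (log2 -5.44, -10.77 to -2.91). PAX8, a kidney and thyroid transcription factor, went the other way with 68 UMIs in U87 and 0 in HEK293 (at least 29.7-fold higher).

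Cell cycle genes went both ways. Of 44 G1/S genes 16 were lower in U87, 0 were higher and 28 lay between (median -0.52, percentile 10.4), with the repair exonuclease gene EXO1 at log2 -3.27 (-4.31 to -2.39) and DTL, a ubiquitin ligase adaptor of the replication phase, at -2.27 (-3.10 to -1.52). The G1/S list lay below the random range with the alternative UMI table (-0.60, percentile 1.79), on reads (-0.56, percentile 1.12) and among genes with at least 0.25 of the overall reads per UMI (-0.52, percentile 1.84). Of 52 G2/M genes 12 were higher and 6 lower (median 0.26, percentile 96.4), with the mitotic kinase AURKA at 1.76 (1.498 to 2.03) and the histone chaperone ANP32E at -4.03 (-4.34 to -3.74, and -1.72 on reads). Of 22 replication-dependent histones 10 were higher and 7 lower (median 0.47, percentile 98.3). HIST1H1C was at 3.08 (2.49 to 3.73, and 1.97 on reads) and HIST1H2AH at -2.57 (-3.76 to -1.56, and -4.65 on reads). Among genes with at least 0.25 of the overall reads per UMI the histone median was -0.16 (percentile 45.0), and read counts gave 0.037 (percentile 75.6).

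Of 20 p53 targets 8 were higher and 2 lower (median 0.87, percentile 99.3). CDKN1A, the cyclin-dependent kinase inhibitor, was at log2 2.86 (2.20 to 3.59) and the death receptor gene FAS at 2.97 (1.81 to 4.37). MDM2, a ubiquitin ligase, was at -3.34 (-4.02 to -2.72) on UMIs and at -0.46 on reads. MTAP, a methionine salvage enzyme next to CDKN2A, had 0 UMIs in U87 and 125 in HEK293 (at least 31.8-fold lower in U87), and the kinase inhibitor CDKN2B had 0 and 84 (at least 21.4-fold lower).

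Lists of metabolism and protein synthesis lay closer to 0. Of 62 nuclear-encoded respiratory chain genes 4 were higher and 3 lower (median 0.29, percentile 98.8), but the median on reads was -0.30 (percentile 22.0), and against HEK293 plate 1 alone 0.14 (percentile 92.9). Of 19 glycolysis genes 6 were higher and 3 lower (median 0.43, percentile 96.0), with pyruvate kinase PKM at 2.09 (2.003 to 2.17) and GAPDH at 1.52 (1.45 to 1.58). The glycolysis list lay above the random range on reads (0.81, percentile 99.5) and against plate 1 alone (0.60, percentile 98.4). Of 79 cytosolic ribosomal protein genes 4 were higher, 4 lower and 71 between (median 0.062, percentile 78.3), with the paralog RPS27L at 3.15 (3.002 to 3.303) and RPS2 at -1.87 (-1.95 to -1.79). On reads the ribosomal median was -0.77, at percentile 0. All 13 mitochondrially encoded genes lay within 2-fold (median -0.40, percentile 5.27), with MT-ATP8 at -0.96 (-1.12 to -0.81). Of 18 translation factors 2 were higher and 1 lower (median 0.19, percentile 80.9), with EIF4B at -2.35 (-2.64 to -2.08, and -1.32 on reads). Of 20 sterol genes 9 were higher and 5 lower (median 0.33, percentile 91.2), with INSIG1 at 2.38 (2.17 to 2.58) and HMGCS1 at -3.14 (-4.05 to -2.36, and -0.83 on reads). The sterol list lay above the random range with the mean of per-cell CPM (0.53, percentile 97.7), against plate 1 alone (0.72, percentile 99.1) and among genes with at least 0.25 of the overall reads per UMI (0.74, percentile 98.65).

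Of 15 chaperone genes 3 were higher and 3 lower (median -0.40, percentile 10.2), with HSPB1 at 2.77 (2.65 to 2.89). The near-identical pair HSPA1A and HSPA1B, which may share reads, was at -3.99 (-4.65 to -3.40) and -3.81 (-4.22 to -3.41), and at -2.17 and -4.55 on reads. Of 15 unfolded protein response genes 2 were higher and 2 lower (median -0.017), with ATF4 at -1.93 (-2.32 to -1.56) and HSPA5 at 1.34 (1.25 to 1.44). Of 16 hypoxia targets 3 were higher and 5 lower (median 0.0037), with ADM, the vasodilator adrenomedullin, at 4.23 (3.67 to 4.85) and PDK1 at -2.80 (-3.48 to -2.17). Of 10 long noncoding RNAs in the list named nuclear-retained, 2 were higher and 5 lower (median -0.72, percentile 8.78), with KCNQ1OT1 at -2.86 (-3.85 to -1.999). Where in the cell these RNAs lie was not measured. Of 7 astroglial and glioma genes 1 was higher and 1 lower (median 0.24), namely the growth factor receptor EGFR at 3.56 (2.43 to 4.93) and MSI1 at 0 UMIs against 136 (at least 34.6-fold lower). Of 6 epithelial genes 2 were higher and 3 lower (median -0.46, but 0.76 and 0.35 against plates 1 and 2 alone, where other members were measured). Of 3 endothelial genes 1 was higher and 2 lower (median -1.20).

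Across 3765 genes with at least 50 CPM in either line the SD of the log2 ratios was 1.94, and Spearman's rho across genes was 0.55. Scaling by TMM or by the median of ratios would add 0.22 or 0.21 to each log2 ratio of U87 over HEK293. Against HEK293 plates 1 and 2 alone some named genes left their counting intervals, with log2 ratios of 5.76 and 3.43 for CTGF, -3.45 and -1.18 for KCNQ1OT1, 2.38 and 0.90 for CD68, -2.09 and -3.41 for PDK1 and 2.66 and 4.01 for HIST1H1C. For genes of 1 HEK293 UMI, such as PLAU (5.74 and 5.29), the floor of 3 counts sets these ratios. U87 fills 1 plate, so line and plate cannot be separated in these libraries.

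**Figure D3:**
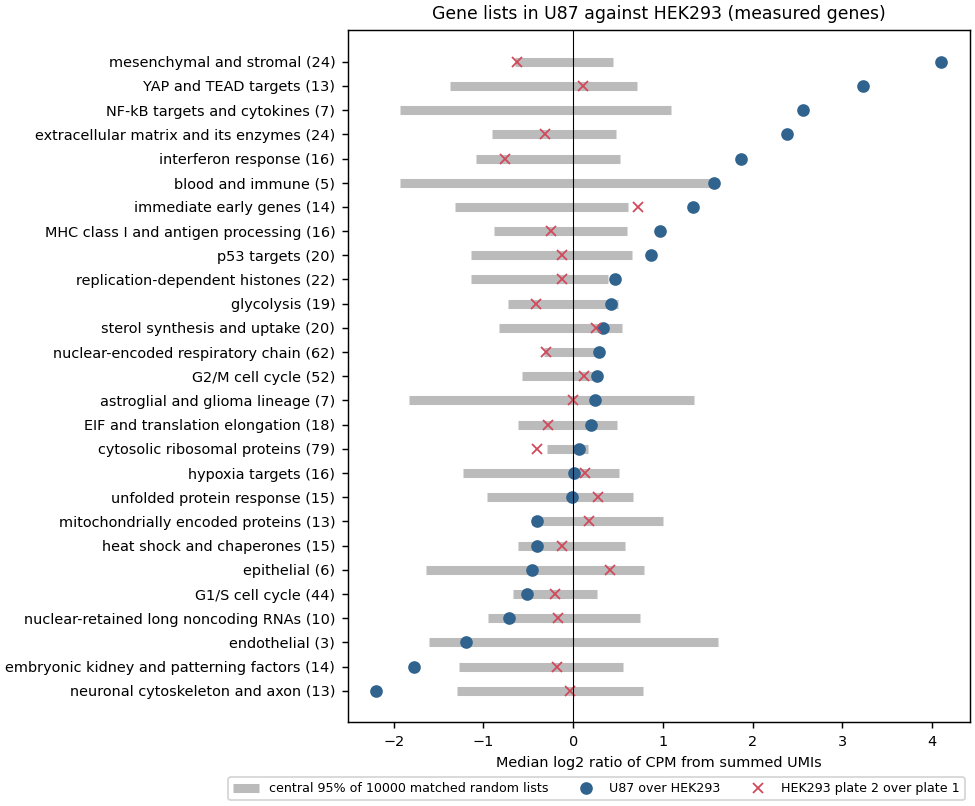
Median log2 ratio of CPM (horizontal) of each gene list, with the number of measured genes in parentheses. Dots give U87 over HEK293, crosses give HEK293 plate 2 over plate 1, and grey bars span the central 95% of 10000 expression-matched random lists for U87 over HEK293; the mesenchymal list lies at 4.10 and the neuronal list at -2.20.

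The 2 HEK293 plates give the spread between plates of the same line, and whether both came from the same culture is not given. Ribosomal protein genes were lower on plate 2 than on plate 1 (median log2 -0.40 over 79 genes, percentile 0), as were respiratory chain genes (-0.30 over 62, percentile 0). All members of both lists lay within 2-fold. Mesenchymal genes (-0.63 over 17, percentile 0.25), interferon response genes (-0.76 over 12, percentile 0.42) and glycolysis genes (-0.42 over 19, percentile 1.04) were lower on plate 2, and immediate early genes were higher (0.73 over 9, percentile 98.985). The SD of log2 ratios across 3469 genes was 0.77 between plates, against 1.94 between lines, and rho was 0.88. On read counts the SD between plates was 0.40, with 2 lists above and 2 below the random range in place of 1 and 5. Of the lists low on UMIs only the ribosomal one stayed low on reads. The mesenchymal (-0.11, percentile 18.0), interferon (-0.21, percentile 14.8), glycolysis (-0.20, percentile 3.46) and respiratory lists (-0.042, percentile 9.80) came inside the range. Immediate early genes did so on reads (0.69, percentile 96.3) and with the alternative UMI table (0.65, percentile 95.2). The lists above it on reads were MHC class I (0.54, percentile 98.9) and G2/M (0.28, percentile 99.2).

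The bulk library serves as the reference for the single-cell protocol in HEK293. Of 13 mitochondrially encoded genes 4 were at least 2-fold higher in the summed single cells and 1 was at least 2-fold lower (median log2 0.37, percentile 94.2), and a group of near-identical loci was much higher in bulk. AKAP9, a centrosomal scaffold, was at a log2 ratio of single cells over bulk of 1.51 (1.46 to 1.56) and MAP1B, a microtubule-associated protein, at 1.49 (1.43 to 1.54). MT-CYB was at 1.45 (1.43 to 1.48), MT-CO2 at 1.40 (1.39 to 1.41) and MT-ND6 at 1.31 (1.25 to 1.37). The corepressor NCOR1 was at 1.39 (1.36 to 1.42), the nuclear noncoding RNA MALAT1 at 1.25 (1.24 to 1.27), ERGIC2 at 1.24, CDK7 at 1.20 and NGLY1 at 1.20. CH507-513H4.5 was at -7.77 (-7.79 to -7.76), and CH507-513H4.3, CH507-513H4.4 and CH507-513H4.6 each at -7.65; with nearly equal counts these loci are uncertain individually. The overlapping neighbours C1orf56 (-4.57) and CDC42SE1 (-4.06) are likewise uncertain. XYLT2, a proteoglycan synthesis enzyme, was at -4.51, the deacetylase complex subunit MTA2 at -4.06, the kinetochore gene SPC24 at -4.03 and the chaperone calreticulin, CALR, at -3.83 (-3.85 to -3.81).

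Across 12154 genes with at least 1 CPM on either side, Spearman's rho between bulk and summed single-cell reads was 0.93 and Pearson's r of log2(CPM + 1) was 0.95. Genes are not independent replicates, so no p-value applies. Plate 1 alone gave rho of 0.91 and plate 2 alone 0.90, while the plates gave 0.90 against each other. Summed UMIs in place of reads gave rho of 0.74 and r of 0.77 over 15671 genes. Bulk held 76394269 reads on 20341 genes, and the summed single cells held 875074338 reads on 20726 genes.

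Against expression-matched random lists, 0 lists were high and 8 were low in single cells over bulk. Kidney and patterning factors had 11 of 18 members at least 2-fold lower and 0 higher (median log2 -1.22, percentile 0.41). YAP and TEAD targets had 8 of 12 lower and 1 higher (-1.45, percentile 1.74), epithelial genes 6 of 10 lower (-1.31, percentile 1.40), replication-dependent histones 10 of 23 lower (-0.88, percentile 1.41) and p53 targets 10 of 23 lower (-0.77, percentile 1.74). Glycolysis (-0.34 over 19, percentile 1.69) and chaperone genes (-0.21 over 16, percentile 0.61) were low as lists, with 2 and 1 members at least 2-fold lower. Ribosomal protein genes lay at -0.046 over 79, or 0.14 under TMM, 0.16 under the median of ratios and 0.016 with plate 1 alone, below nearly all random lists in each case (percentiles 0.015, 0, 0 and 0.045). On UMIs the kidney, epithelial, YAP and histone medians were positive at 0.73, 0.37, 0.99 and 0.74, and these 4 lists lay inside the random range. With either plate alone, the epithelial list (percentiles 2.73 and 35.1), the YAP list (7.04 and 2.68) and the glycolysis list (6.43 and 3.26) also lay inside it. The p53 list did so with plate 2 alone (percentile 8.07), with every listed gene of at least 1 count (3.17) and under the median of ratios (2.60). On UMIs the glycolysis, chaperone and ribosomal lists did so too (percentiles 2.82, 24.0 and 4.45). TMM and the median of ratios would add 0.19 and 0.21 to each ratio alike, so percentiles change under them only through the matching of random lists.

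Cell-to-cell variation within a line addresses which gene groups vary in their summed UMIs between cells of the same kind. Such a sum does not show whether the members vary together, since 1 member can carry it. In U87 the summed UMIs of 52 G2/M genes, which include mitotic kinases and cyclins, had a variance 26.4 times their mean (Fano factor) over 85 cells thinned to 18500 UMIs, against a central 95% of 1.46 to 5.92 for matched random lists (percentile 100). Replication-dependent histones had a Fano factor of 18.2 (percentile 99.9), G1/S genes 6.98 (percentile 99.5) and respiratory chain genes 5.74 (percentile 97.6). HIST1H4C, the single histone gene among the 12 most variable in U87, had a Fano factor of 26.2 with a mean of 10.3 thinned UMIs and was seen in 84 of 85 cells. The whole histone list had a mean of 17.6, so HIST1H4C alone supplied much of the list's UMIs and variance. Unfolded protein response genes (7.99, percentile 95.8) and YAP and TEAD targets (5.63, percentile 96.7) lay inside the random range. The former lay above it without the well filter, where the thinning depth was also lower (percentile 99.5). It did so too with the alternative UMI table (98.9) and among genes with at least 0.25 of the overall reads per UMI (99.8).

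In HEK293, over 121 cells, histones had a Fano factor of 26.3 (percentile 100), ribosomal protein genes 39.0 (percentile 100) and kidney and patterning factors 17.5 (percentile 97.9). G2/M genes had 8.69 (percentile 83.9) and G1/S genes 3.84 (percentile 14.4). Ribosomal protein genes lay inside the random range within each plate, at percentile 93.3 for plate 1 and 7.72 for plate 2. Kidney and patterning factors did so on plate 1 (percentile 73.8) and after a second random thinning of both plates (percentile 95.4), and histones on plate 2 (percentile 96.1). Among genes with at least 0.25 of the overall reads per UMI, G2/M genes of HEK293 reached percentile 99.65. Without the well filter, the histone list of HEK293 and the G1/S, histone and respiratory lists of U87 fell inside the random range, at percentiles 74.9, 93.5, 97.2 and 84.1. That setting also lowered the thinning depth of every cell, to a median of 511 genes per cell in HEK293 and 514 in U87. Added wells and lower depth are therefore not separated there.

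Single genes of highest Fano factor in HEK293 were BCDIN3D-AS1 (65.1), CARS2 (60.6), AC012370.3 (60.1), ZBTB3 (56.1), FLJ37453 (49.8), KCNK6 (48.9), PIAS3 (48.1), RP11-20B24.4 (42.0), LL22NC03-86G7.1 (41.5), RP13-890H12.2 (41.5), AP000892.6 (41.4) and FMNL3 (41.2). BCDIN3D-AS1 had UMIs in 6 of 121 cells, and 89.5% of them lay in 1 cell at 4.47 reads per UMI, where the whole cell had 196. CARS2, a mitochondrial cysteinyl-tRNA synthetase, had UMIs in 48 cells. In U87 the leading genes after CTD-3193O13.12 (31.7), RP11-545I5.3 (29.3), CTC-327F10.4 (28.0) and TRIM13 (26.4) were HIST1H4C, ZNF562 (26.0), GPRC5B (25.6), SLC7A6OS (25.4), FARP1 (24.5), ZSCAN30 (24.0) and BEST1 (23.9), with 1 further clone-named transcript among the 12. CTC-327F10.4 had UMIs in 3 of 85 cells and ZSCAN30 in 4, whereas BEST1 had a mean of 138 thinned UMIs and was seen in all 85. The alternative UMI table held 6.03 times as many UMIs of BEST1, so its level depends on the table. Over all tested genes the median Fano factor was 1.75 in HEK293 (4528 genes) and 1.22 in U87 (4296 genes).

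**Figure D4:**
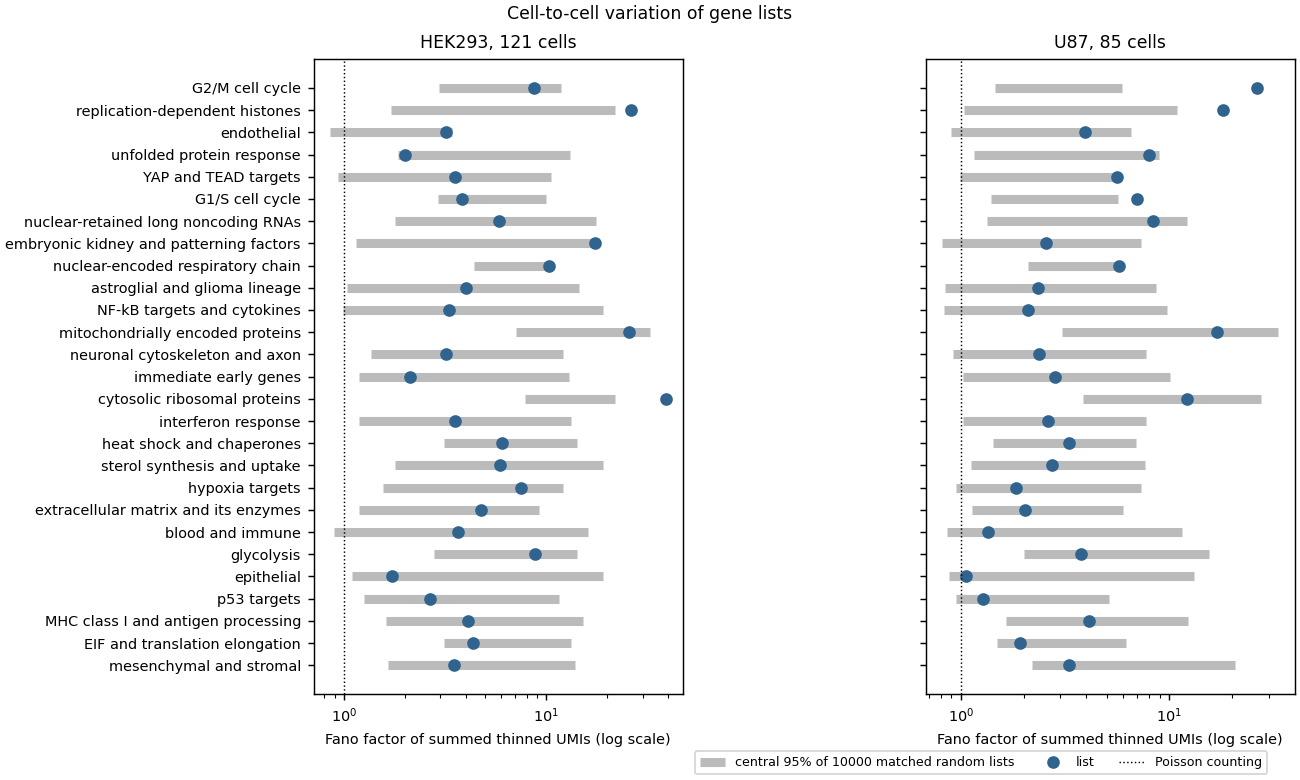
Fano factor (variance over mean across cells, log scale) of the summed thinned UMIs of each gene list in HEK293 and in U87. Dots are lists, grey bars span the central 95% of 10000 matched random lists and the dotted line marks Poisson counting at 1; in U87 the G2/M list lies at 26.4 and in HEK293 the ribosomal list at 39.0.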

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

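All tests in this part were chosen after the result was seen. Wells left out for low totals enter no comparison, yet they held UMIs above the limit that a count of 0 allows. The median was 1191 UMIs in 18 such wells of HEK293 plate 1, 622 in 40 wells of HEK293 plate 2 and 814 in 1 well of U87. In mixture wells it was 2298 in 1 well of plate 2 of the 15x SMRT, 12x Nextera, SPRI condition, 722.5 in 10 wells of 15x SMRT, 8x Nextera, SPRI, 1654.5 in 6 wells of 12x SMRT, 12x Nextera, SPRI and 35 in 15 wells of 12x SMRT, 12x Nextera, Silane. The left-out HEK293 wells had a median of 10.4 reads per UMI, against 204 in kept wells. In the left-out mixture wells, molecules from other wells of the plate may be the source, since their human share lay a median of 6.61 percentage points from the plate's share, though the distances ran from 0.205 to 44.1.

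In the mixture wells the minor species held a median of 16.7% of UMIs over the 15x SMRT, 12x Nextera, SPRI plates but 3.37% of reads. A pair of cells of different species in a well would give both species similar reads per UMI, which the highest plate row median of minor over major, 0.661 (0.370 to 0.717), argues against as the main source on all plates. Whether every well of a plate held the same count of carried-over UMIs of a species, as the whole source, is not decided on the 15x SMRT, 12x Nextera, SPRI plates. Minor UMIs lay at a median of at least 1.32 times the 5th percentile of that species on each plate (lowest bound 1.22). The low end of a species comes mostly from the wells where it is minor, so any spread in yield between wells raises this ratio. Against the higher of both species' percentiles the medians were only 1.01 times (0.846 to 1.24) with 8x Nextera and 1.05 times (0.884 to 1.34) with Silane. That measure pools wells of either major species. Row correlations of minor and major UMIs ran from -0.329 to 0.853 on the 15x SMRT, 12x Nextera, SPRI plates, whose rows hold wells of either major species. On the other plates, whose rows were mostly human or mostly mouse, every row correlation was at least 0.664. Equal counts in every well would not rise with the major species, which argues against them as the whole source on those plates. A spread in yield between wells would scale both species, so an equal number before such losses stays possible. Reads assigned to the wrong genome and carry-over in proportion to a well's own material cannot be told apart, because both predict similar minor shares of reads on all plates (highest over lowest 1.49), and no biological explanation was tested.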

How the results depend on the processing

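Chosen after seeing the data were reads instead of UMIs for mixture wells and genes with at least 0.25 of the overall reads per UMI. No paired analysis was possible because each group counts as 1 sample and no result comes from a test. Of 456 alternative values of results that answer a comparison, 331 stayed on the same side of the random range or within their interval, 70 moved, 46 came to lie inside the random range and 9 reversed. Of 1134 for named genes 927 stayed, 203 moved and 4 reversed. Of 750 for the other lists, which lay inside the random range or compare the HEK293 plates, 700 stayed, 7 moved, 6 came to lie inside the range and 37 came to lie outside it. TMM and the median of ratios shift a list and its random lists alike. List values under them stay by construction unless the matching of random lists changes. Unless the construction of an alternative shows it, the cause was not tested. Depth limits the lists with few UMIs, such as the endothelial list with 3 measured genes.

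For mixture plates the order is 15x SMRT, 12x Nextera, SPRI plates 1 and 2, 15x SMRT, 8x Nextera, SPRI, then 12x SMRT, 12x Nextera with SPRI and with Silane. With a threshold of 5% the mixed share was 100, 100, 51.2 and 73.3% on the first 4 plates, and with 20% it was 22.9, 14.7, 1.16, 10 and 0%, as the threshold itself implies. With species scaled by their own upper wells it was 95.8, 96.8, 1.16, 32.2 and 1.23%, and with reads 2.08, 0, 0, 5.56 and 0%. With reads the median minor share was 3.48, 3.305, 2.63, 3.53 and 2.37%, the median total 1034080, 881034.5, 351960.5, 656327.5 and 443663, and the median human share 4.74, 4.67, 8.03, 12.2 and 5.94%.

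The median count per HEK293 cell was 24494 without the well filter, 47362.5 with umi0, 5875055 with reads and 31202.5 without plate 1, and per U87 cell 38512 with umi0 and 2254448 with reads. Without the filter a HEK293 cell had 4292.5 genes. Thinned genes per cell were 511, 3990.5, 3646 and 4170 in HEK293 and 514, 4206, 4124 and 4932 in U87 without the filter, with the 25% filter, with umi0 and with reads, where the thinning depth itself differs. Reads per UMI were 183 in HEK293 without the filter, 125 with umi0 and 55.8 in U87 with umi0.

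For U87 over HEK293 the neuronal median was -0.064 with all listed genes, -0.81 with umi0 and -0.99 with reads, and the blood and immune median 1.79 under TMM and 1.78 under the median of ratios. The MHC class I median was 0.38 with reads. The histone median was 0.57 with the mean of per-cell CPM, 0.39 with all listed genes, 0.037 with reads and, reversed, -0.16 with genes of at least 0.25 of the overall reads per UMI. The respiratory chain median was 0.14 with umi0, 0.14 without plate 2, 0.32 with genes of at least 0.25 of the overall reads per UMI and, reversed, -0.30 with reads. With all listed genes, 1 list lay below the random range. Lists that came to lie outside it were glycolysis with reads (0.81) and without plate 2 (0.60), sterol genes with the mean of per-cell CPM (0.53), without plate 2 (0.72) and with genes of at least 0.25 of the overall reads per UMI (0.74), G1/S genes with umi0 (-0.60), reads (-0.56) and genes of at least 0.25 of the overall reads per UMI (-0.52), and ribosomal genes with reads (-0.77). The log2 ratio reversed for ALDH1L1 without plate 1 (0.012), and with reads for SLC16A3 (3.27), MT-ND5 (0.32) and EIF5A (0.73). Between HEK293 plates the SD was 0.66 with umi0 and 0.40 with reads, which put 2 lists above and 2 below the random range. With reads the mesenchymal (-0.11), interferon (-0.21), immediate early (0.69), glycolysis (-0.20) and respiratory lists (-0.042) came inside it, and MHC class I (0.54) and G2/M genes (0.28) came to lie outside. With umi0 immediate early genes (0.65) came inside and unfolded protein response genes (0.37) came to lie outside.

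For bulk, Spearman's rho was 0.90 with plate 2 alone and 0.74 with UMIs, and Pearson's r was 0.93 with plate 2 alone, 0.97 with no filter on low values, 0.93 with a pseudocount of 0.1 and 0.77 with UMIs. With UMIs the single-cell over bulk medians of kidney (0.73), epithelial (0.37), YAP (0.99) and histone genes (0.74) reversed, and those of glycolysis (-0.66), chaperone (-0.32) and ribosomal genes (-1.50) came inside the random range. With the mean of per-cell CPM, epithelial (-0.80), YAP (-1.45) and glycolysis genes (-0.15) did so, with all listed genes epithelial (-1.91), p53 (-0.78), YAP (-1.66) and histone genes (-0.91), with plate 1 epithelial (-1.33), YAP (-1.47), glycolysis (-0.20) and histone genes (-0.87), with plate 2 epithelial (-0.45), p53 (-0.75), YAP (-2.51) and glycolysis genes (-0.31), and with the median of ratios p53 targets (-0.57). The ribosomal median had the opposite sign under TMM (0.14), the median of ratios (0.16) and with plate 1 (0.016), since it lies near 0. Lists that came to lie outside the range were astroglial genes with all listed genes (-2.52) and plate 1 (-2.23), NF-kB targets with plate 2 (-4.43) and UMIs (-0.058), G2/M genes with plate 1 (-0.27), mitochondrially encoded genes with the mean of per-cell CPM (0.51) and UMIs (2.76), and translation factors with plate 2 (-0.14). The mean of per-cell CPM put 1 list above and 5 below the random range, all listed genes put 5 below, and UMIs put 1 above and 2 below.

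Variation is given as the Fano factor over the median of random lists. The thinning depth itself differs without the well filter, with the 25% filter and with umi0, and is far lower without the filter. In HEK293 the kidney list came inside the random range with the 25% filter (7.58), a thinning depth at the 25th percentile (7.98), umi0 (5.24), a second random thinning (6.01) and plate 1 (1.82). The histone list did so without the well filter (1.20) and with plate 2 (6.97), and the ribosomal list with umi0 (1.97), genes of at least 0.25 of the overall reads per UMI (1.49), plate 1 (1.71) and plate 2 (0.68). Either plate alone left 1 list above the range. In U87 the G1/S (1.27), histone (1.49) and respiratory lists (1.17) came inside it without the well filter, and the respiratory list with genes of at least 0.25 of the overall reads per UMI (2.07). In U87 the unfolded protein response list came to lie above it without the well filter (1.54), with umi0 (3.95) and with genes of at least 0.25 of the overall reads per UMI (5.03), hypoxia targets without the filter (1.504), interferon genes with genes of at least 0.25 of the overall reads per UMI (1.98), the endothelial list with the 25th percentile depth (7.41), and translation factors below it (0.465) with that depth. In HEK293 the G2/M list came to lie above it with umi0 (2.46) and genes of at least 0.25 of the overall reads per UMI (2.79), mitochondrially encoded genes with the 25th percentile depth (2.23), and the respiratory list without the filter (1.75), with that depth (1.88) and with genes of at least 0.25 of the overall reads per UMI (1.61). The HEK293 lists that came to lie below it were unfolded protein response genes without the filter (0.697) and with plate 2 (0.295), G1/S genes without the filter (0.705) and the respiratory list with plate 2 (0.462).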

Other observations

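All tests in this part were chosen after the result was seen. Genes at 0 UMIs in U87 with at least 50 UMIs in HEK293 numbered 118 of 6243 and included members of a cancer-testis antigen family on chromosome X. MAGEA3 had 98 UMIs in HEK293, MAGEA6 102, MAGEA2 62, MAGEA2B 62 and MAGEA12 53, all with 0 in U87. These paralogs may share reads, so their individual values are uncertain, and they were chosen after their values were seen, as was HOXA9, a homeobox gene with 239 UMIs in HEK293 and 0 in U87.

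Median log2 ratios of U87 over HEK293 differed between chromosomes. Genes of chromosome 20 had a median of 0.48, those of chromosome 8 of 0.28, of chromosome 9 of 0.26, of chromosome 7 of 0.14 and of chromosome 19 of 0.13, each above all 10000 matched random lists. Those of chromosomes 3 (0.025, percentile 99.9), 15 (0.10, percentile 99.8) and 5 (0.011, percentile 99.2) also lay above the random range. Genes of chromosome 1 had a median of -0.60 (percentile 0), of chromosome 17 of -0.45 (percentile 0.010), of chromosome 22 of -0.50 (percentile 0.58) and of chromosome X of -0.47 (percentile 0.33). Chromosomes also differed between the HEK293 plates, where the medians of plate 2 over plate 1 were -0.19 for chromosome 19 (percentile 0), -0.19 for 22 (percentile 0.050), -0.18 for X (percentile 0.14), -0.22 for 21 (percentile 1.1) and 0.14 for 13 (percentile 99.6). Across genes, the log2 ratio of single cells over bulk correlated with GC content at a Spearman's rho of -0.12 and with gene length at -0.23, for 11009 of 12154 genes with a value. Between the HEK293 plates the same genes gave a rho of -0.10 with GC content and 0.057 with gene length.

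MTAP (chromosome 9, 21802543 to 21937651, GRCh38), CDKN2A (21967753 to 21995301) and CDKN2B (22002903 to 22009363) are neighbours, and each had 0 UMIs and 0 reads in U87, against 125, 1025 and 84 UMIs in HEK293. The low block reached further, since KLHL9 had 0 UMIs and 0 reads in U87 (35.1 UMIs expected at the HEK293 level) and FOCAD 1 UMI (22.2 expected), both chosen after their values were seen. Neighbouring genes at 0 by chance is argued against, because MTAP, CDKN2A and CDKN2B were fixed before the data were examined, and in draws of genes of like HEK293 UMIs MTAP's substitute and CDKN2B's were both at 0 in 2 of 10000 (at most 0.0722%). Lower depth is argued against by the smallest expected number, 64.2 UMIs for CDKN2B at the HEK293 level, and loss of reads to near-identical copies by at least 84 UMIs for each gene in HEK293. Deletion and silencing of the region in U87, and an effect of its single plate, were not tested and stay open.

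The single genes of highest Fano factor had few reads behind each UMI in their highest cell. Over the 12 genes of HEK293 the median ratio of the gene's reads per UMI to that of the whole cell was 0.0236, against 0.249 over all tested genes, and over the 12 genes of U87 it was 0.0359, against 0.53. Many UMIs with few reads each in single wells may therefore account for the high Fano factors of these genes. HIST1H4C (0.43) and BEST1 (0.28) in U87 had higher ratios. A biological origin was not tested.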
